A study of Canis lupus familiaris with 12 samples.

How the data were processed

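Genomic DNA of 7 FL and 5 MZL tumours was compared with skin DNA of the same dog on 12 arrays of a 2-colour canine design, on 8 slides, with 1 array per dog and no dye swap. FL 2, FL 4 and MZL 4 shared a slide, the only one with both types. Per the file headers, the images were read with Agilent Feature Extraction 11.5.1.1, and the processed signal of each channel is an intensity after background subtraction, spatial detrending and linear dye normalization. Per the file headers, the median signals of spot and background are raw pixel intensity values. The log10 ratio in the deposited files is that of red over green processed signals, per the file headers. The deposited value table holds log2 ratios of tumour over skin for 98647 probes, and the method behind its values is not stated in the labels. The files place the probes on CanFam3.1.

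Of 180880 spots per array, 6946 control spots were left out, as were spots marked as outliers. The log2 ratio of red over green processed signals was averaged over the spots of each probe, which left 162404 autosomal and 8646 X probes, and was centred on the autosomal median of the array. Probe noise was taken from differences between neighbouring probes. The limit of the scanner software on noise was exceeded by 9 arrays, and 4 arrays fell short of its limit on signal over background. Precision is limited by the number of arrays.

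Segments were found per chromosome by exact optimal partitioning of values winsorised at 4 SD around the running median of 11 probes, with a penalty of 2 times the log of the number of probes in units of the noise variance and at least 3 probes per segment. A segment of 5 or more probes with a mean log2 ratio of 0.2 or beyond in either direction was called, and adjacent calls of 1 sign were merged. Bins of 1 Mb held 20 or more probes. A bin was called in a tumour when at least 50% of its probes lay in calls of 1 sign. Numbers of calls, altered shares and chromosome means were compared between the types by two-sided exact permutation tests. Recurrence was tested by shifting the calls of each tumour along the joined autosomes, with 10000 draws and family-wise one-sided p. Bin means were compared with limma, with eBayes for FL against MZL and treat with a minimum log2 ratio of 0.1 for tumour against skin. P-values over bins, chromosomes and fixed chromosomes were adjusted by the Benjamini-Hochberg method. Gains of chromosomes 13 and 31 and losses of 11, 14 and 26 were fixed before the data were examined and compared with Fisher's exact test. The definition of a whole-chromosome call in that test, 50% or more of the length, was set after the data were seen.

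Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6, numba 0.67.0, matplotlib 3.10.9, R 4.3.3, limma 3.58.1 and statmod 1.5.0.

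The steps were tested on simulated data. In independent noise with 197 planted changes per array, the segmentation made 0 false calls. No wave was simulated, so this count does not cover calls that a wave may cause. At the median noise, 95.2% of simulated changes of 100 probes and log2 0.3 were recovered, 90.9% of those of 30 probes and log2 0.5, and 0% of those of 30 probes and log2 0.3. The recurrence test on FL found a region in 1.5% of null sets. These sets were made by the same random shifts that the test uses. The rate thus does not cover a wave or probe effect that arrays share at the same positions. For FL against MZL, limma recovered 66% of bins changed by log2 0.2 and 90% of those changed by 0.4. It also called 12 of 2131 unchanged bins. The bins were simulated independently and without a wave, so recovery in the real bins may differ.

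Alternatives planned before the data were examined were call thresholds of 0.15 and 0.3, a minimum of 10 probes, penalties of 1 and 4 times the log, centring on the mode, normexp with an offset of 50, the deposited value table, removal of saturated or dim probes, bins of 500 kb, bin medians, a running median of 21 probes, array weights, the slide as a random or fixed block, a trended robust eBayes, other minimum changes and leaving out each tumour. Normexp used median in place of mean spot signals, since the files hold no mean signals. A correction for GC content was not run, since the files used here hold no probe sequences.

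A wave correction was added after the data were seen. The value table differed from the scanner ratios by an array slope times 1 probe covariate shared by all arrays (absolute correlations of 0.993 or more, with FL 5 opposite in sign). The covariate was taken from the difference in MZL 5, the array with the largest slope. It was predicted for all autosomal probes by a linear model on running means of the skin signals, and its fitted part was subtracted from each array. Trained on even chromosomes, the model explained a share of 0.434 of the variance of the covariate on odd ones. Values given with the wave removed are those after this correction, which may leave part of the wave. In all, 6 versions of this model were tried, and their effects on the calls were seen before 1 was chosen. Other additions made after the data were seen were scanner ratios at the probes of the value table, limma on autosomes only, counts of any call on a chromosome, and the definitions of large calls (5 Mb or more), deep focal losses (-0.5 or lower, up to 3 Mb) and calls kept after correction (50% or more of the probes).

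Regions were named by a rule fixed before the data were examined, as up to 8 recurrent regions per type and sign by number of tumours and then mean log2 ratio, and the 5 bins of smallest p where none passed. The rule also named the fixed chromosomes, X and a few genes, among them MYC, KIT, CDKN2A, TRAF3, BCL2 and BCL6. Comparisons of genes, gene lists and antigen receptor loci were left out, since the files do not pair probes with genes and the gene table at hand is of another assembly (UU_Cfam_GSD_1.0). That table was used only for the chromosome of a gene, which it gave for 87 of 88 listed genes.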

Results

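Copy number was measured in 12 canine lymphomas, 7 follicular lymphomas (FL) and 5 marginal zone lymphomas (MZL), by comparative genomic hybridisation on arrays that carried 171050 probes with a position on CanFam3.1. Tumour DNA (cyanine 5) and skin DNA of the same dog (cyanine 3) were hybridised together on each array, so that a log2 ratio of 0 stands for equal dose. The probes lay a median of 12.7 kb apart. The noise of a single probe ranged from a log2 SD of 0.26 in FL 4 to 0.43 in FL 5, and the signal over background in the tumour channel from 17.2 in MZL 3 to 100.2 in FL 3. Each tumour was hybridised once, and the number of arrays limits the precision.

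Most tumours carried few large changes. Gains or losses covered between 0.36% of the autosomes in FL 6 and 10.3% in MZL 1 in 11 of the tumours, and 37.2% in MZL 5. Losses outnumbered gains, with 526 called losses and 99 called gains over the 12 tumours, of which MZL 5 alone held 224 and 53. The profiles held a wave along the chromosomes that was strongest in MZL 5. This wave was then removed, a step chosen after the data were seen. After its removal, 123 of the losses and 38 of the gains were still called over most of their probes. The altered share of MZL 5 was then 7.61%. Other arrays were affected as well. Still called were 0 of the 43 losses of MZL 1 and 4 of the 66 of FL 1. In MZL 5 they were 44 of 224, and in FL 4 24 of 26. The 10.3% of MZL 1 is thus not read as tumour change alone.

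**Figure D1:**
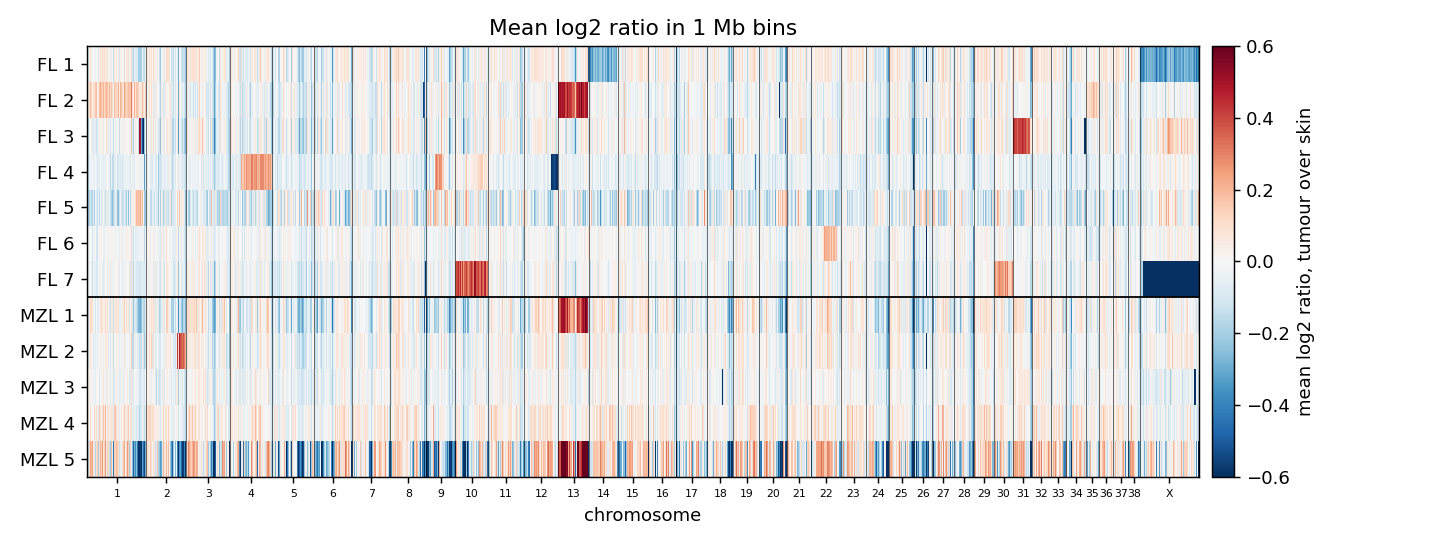
Mean log2 ratio of tumour over skin in 1 Mb bins along the autosomes and X (columns) for the 7 FL and 5 MZL tumours (rows), with gains in red and losses in blue. Chromosome 13 was gained in FL 2, MZL 1 and MZL 5, and X was low in FL 1 and FL 7.

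The labels name 2 lymphoma types, and the first comparison asked whether they differed in the amount of copy number change. FL tumours held 5.43 ± 4.72 called gains (SD, n = 7) and MZL tumours 12.2 ± 22.9 (SD, n = 5), a difference that exact permutation of the type labels gave with p = 0.689. The number of losses was 30.1 ± 21.4 in FL and 63.0 ± 90.8 in MZL (SD, exact permutation p = 0.506, two-sided as the other tests of this paragraph). The gained share of the autosomes was 1.96% ± 1.88 in FL and 3.74% ± 6.44 in MZL (SD, exact permutation p = 0.663). The lost share was 2.76% ± 2.21 in FL and 6.75% ± 8.98 in MZL (SD, exact permutation p = 0.312). The altered share was 4.72% ± 2.14 in FL and 10.5% ± 15.4 in MZL (SD, exact permutation p = 0.439). All 5 differences were smaller than the spread among MZL tumours. All 5 rested on MZL 5. Without it FL held more gains by 3.43, more losses by 7.39, a gained share larger by 1.05 percentage points and an altered share larger by 0.90 percentage points, and the lost share differed by -0.155 percentage points (exact permutation p = 0.918). The lost and altered shares were also larger in FL in the value table, by 1.19 and 2.39 percentage points, and with the wave removed.

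**Figure D2:**
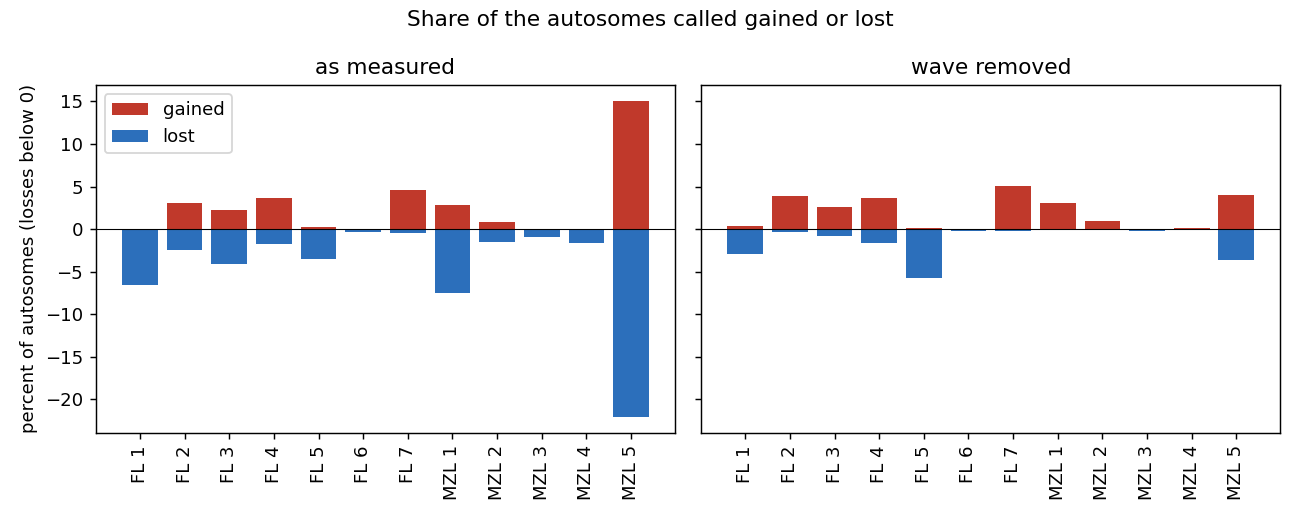
Percent of the autosomes called gained (red, above 0) or lost (blue, below 0) in each tumour, as measured (left) and with the wave removed (right). The altered share of MZL 5 was 37.2% as measured and 7.61% with the wave removed.

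Gains over 50% or more of a chromosome were found in 6 tumours. Chromosome 13, which holds MYC and KIT in the gene table, was gained in FL 2, MZL 1 and MZL 5 with mean log2 ratios of 0.45, 0.39 and 0.48. FL 3 gained chromosome 31 (0.38). FL 7 gained chromosome 10 (0.38), on which the gene table places MDM2, CDK4, REL, STAT6, EP300, TNFRSF13C and FBXO11, and 73.2% of chromosome 30 (0.22), which holds B2M, a gain that was not called at a threshold of 0.3. These means kept their sign in each normalization tried. They changed by less than the SD within the type, which the gained tumours themselves widen. Chromosome 13 in MZL 5 fell from 0.48 to 0.29 with normexp. FL 4 gained 69.8% of chromosome 4 (0.16), which was not called with normexp or at a threshold of 0.3. Fisher's exact test (two-sided) found chromosome 13 gained in 1 FL and 2 MZL tumours (p = 0.523, adjusted p = 1). A gain over at least 50% of chromosome 31 was called in 1 FL and 1 MZL tumour (exact p = 1), and the call in MZL 5 was absent after the wave was removed.

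Losses of whole chromosomes were rarer. FL 1 lost chromosome 14 (mean log2 ratio -0.28), which holds CDK6, and X along its whole length (-0.32). In MZL 5, losses covered 70.8% of chromosome 9 and 51.1% of chromosome 24, and gains 61.1% of chromosome 22, but with the wave removed none of them reached 50%. Chromosome 11, which holds CDKN2A, and chromosome 26 were not lost over 50% or more of their length in any tumour, but at a threshold of 0.15 chromosome 26 was, in 2 MZL and 0 FL tumours (Fisher's exact test, p = 0.152, adjusted p = 0.758). The loss of chromosome 14 in 1 FL and 0 MZL tumours did not separate the types (Fisher's exact test, p = 1), and with a call threshold of 0.3 it was not called. X was low in FL 7 as well (-0.88), but not over its whole length. The match of FL 7 to its skin stays open, so its low X is not taken as a loss here. BTK, KDM6A and GPR34 lie on X. TRAF3 on chromosome 8, BCL2 on 1 and BCL6 on 34 had no call over their whole chromosome, and calls at these genes were not analysed here because the files do not pair probes with genes.

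**Figure D3:**
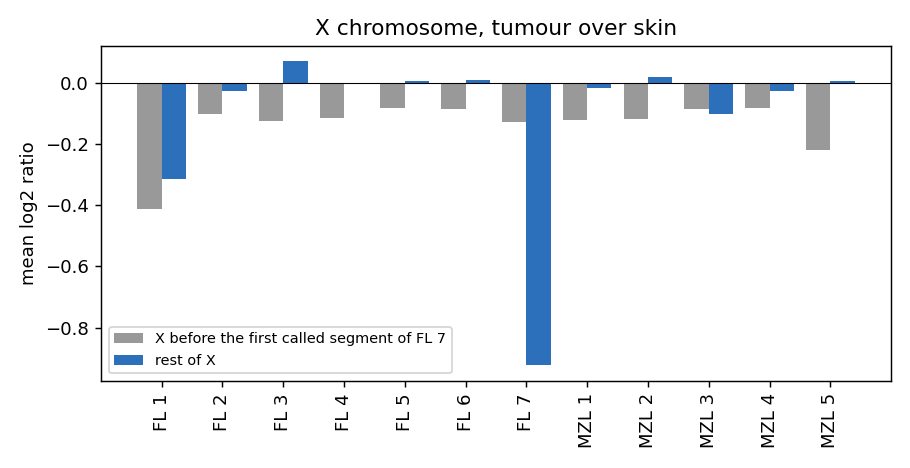
Mean log2 ratio of tumour over skin on X in each tumour, before the first X segment called in FL 7 (grey) and over the rest of X (blue). The rest of X stood at -0.92 in FL 7 and -0.31 in FL 1.

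Larger parts of chromosomes changed in single tumours. FL 3 gained chromosome 1 from 108150148 to 114417351 (mean log2 ratio 0.51) and lost the adjoining stretch from 114428628 to 121963320 (-0.58). It also lost the end of chromosome 34 from 36960453 to 42095540 (-0.69). FL 4 gained most of chromosome 4 from 35074575 to 86034611 (0.25) and chromosome 9 from 19848052 to 37731824 (0.26), and lost chromosome 12 from 58038631 to 72475926 (-0.59). MZL 2 gained chromosome 2 from 71193472 to 85421278 (0.35). With normexp and at a threshold of 0.3, both gains of FL 4 were not called, and 46.2% of the bins of the MZL 2 gain were. These stretches were chosen after their values were seen, from calls of 5 Mb or more that were still called with the wave removed.

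The next comparison asked which regions were lost or gained in more tumours than chance placement gives. No gained region recurred in FL, in MZL or in all 12 tumours (cyclic-shift permutation, one-sided, smallest family-wise p = 0.927 in FL, 0.919 in MZL and 0.627 in all). Recurrent losses lay in 9 regions in FL, 11 in MZL and 16 in all tumours together. Chromosome 26 held the deepest of them. Its bins from 26000001 to 28000000 had a mean log2 ratio of -0.52 ± 0.36 in FL (SD, n = 7), with 6 tumours called at the bin of highest frequency (permutation p = 0.0001, the smallest the permutations can give). In MZL the bin from 27000001 to 28000000 stood at -0.91 ± 0.56 (SD, n = 5) and was called in all 5 tumours (permutation p = 0.0003).

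Other recurrent losses in FL lay on chromosome 28 from 40000001 to 41000000 and chromosome 17 from 1 to 2000000 (6 tumours each at the bin of highest frequency), and on chromosome 25 from 51000001 to 52000000 (5 tumours). Chromosome 8 from 72000001 to 73000000, 34 from 11000001 to 12000000, 20 from 57000001 to 58000000 and 3 from 59000001 to 61000000 were each called in 4 FL tumours. In MZL, 5 regions had all 5 tumours called at the bin of highest frequency, though not always over the whole region. They lay on chromosome 28 from 39000001 to 41000000, 24 from 45000001 to 48000000, 20 from 55000001 to 58000000, 10 from 17000001 to 19000000 and 9 from 48000001 to 52000000. The start of chromosome 9 up to 1000000 and chromosome 8 from 72000001 to 73000000 were called in 4 MZL tumours. With the wave removed, 1 recurrent loss was left in FL and 1 in MZL, both on chromosome 26. A gain then recurred in MZL, on chromosome 5 from 77000001 to 79000000 (4 tumours at the bin of highest frequency, permutation p = 0.0002). The correction could also turn signs. Chromosome 20 from 57000001 to 58000000 was called lost as measured in FL 1, MZL 1 and MZL 5, among others. With the wave removed it was called gained in FL 1, FL 3, MZL 1 and MZL 5. Gains seen only with the wave removed may thus come from the correction, which was not tested. The deposited value table, whose values carry a correction of their own, also gave 1 region in FL and 1 in MZL.

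Short deep losses, of up to 3 Mb with a mean log2 ratio of -0.5 or lower, were most frequent on 3 chromosomes. They were looked for after the data were seen, and are counted here only where most of their probes were still called with the wave removed. On chromosome 26, between 25527682 and 27631338, they were found in 11 tumours, all but MZL 1, with means from -0.50 to -1.57. On chromosome 8, between 70633890 and 74320310, they were found in 4 FL and 1 MZL tumours, with means from -0.69 to -1.64. On chromosome 17, between 37478726 and 37849067, they were found in 3 FL and 2 MZL tumours, with means from -1.30 to -2.50. FL 2 was not counted there, since only 31.6% of the probes of its longer call were still called. From 37686380 to 37849067, with the wave removed, the mean of FL 2 was -1.99. Chromosomes 26, 17 and 8 held 12, 7 and 5 of the 71 losses counted, and the other 47 lay on other autosomes, at most 4 on each (chromosomes 9 and 18). Without MZL 5, 23 of 45 lay on other autosomes. FL 7, whose match to its skin stays open, is among the tumours counted on chromosomes 26 and 8.

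**Figure D4:**
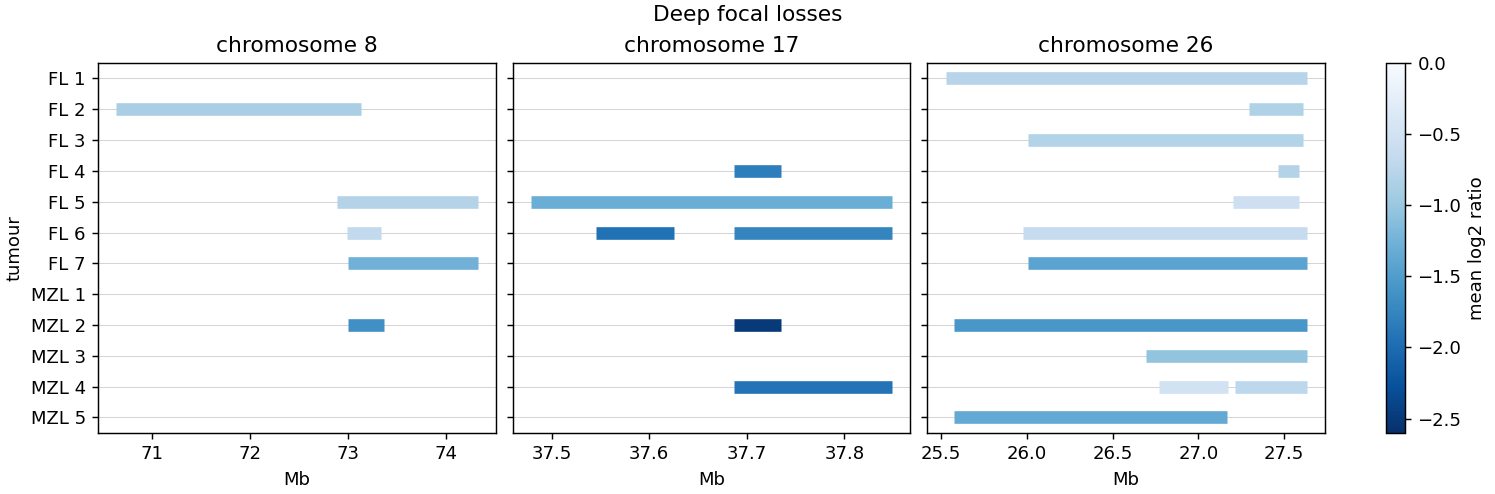
Deep focal losses on chromosomes 8, 17 and 26 that were still called with the wave removed, by tumour (rows) and position in Mb on CanFam3.1, shaded by mean log2 ratio. On chromosome 26 they were found in 11 of the 12 tumours.

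The last comparisons asked where the copy number of FL and MZL differed along the genome. No 1 Mb bin of 2331 passed an adjusted p of 0.05 in limma, and 467 had an unadjusted p under 0.05. The 5 bins of smallest p on different chromosomes, which did not pass (limma adjusted p = 0.237 each), were all lower in FL. They lay on chromosomes 3 from 20000001 (FL minus MZL log2 difference -0.14), 16 from 39000001 (-0.12), 11 from 46000001 (-0.15), 33 from 20000001 (-0.13) and 14 from 30000001 (-0.17). On the slide that held 2 FL tumours and 1 MZL tumour, these differences ranged from -0.09 to -0.21, but 31 of 39 chromosomes were lower in FL there and the MZL arm is 1 array, so they are no separate evidence.

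No chromosome differed between the types after adjustment (exact permutation, two-sided), and the smallest p was 0.0164 for chromosome 14 (adjusted p = 0.226), with a mean of -0.07 ± 0.10 in FL and 0.04 ± 0.03 in MZL (SD). For chromosome 13 the means were 0.04 ± 0.18 and 0.18 ± 0.24 (exact permutation p = 0.261). X stood at -0.17 ± 0.34 in FL and -0.03 ± 0.04 in MZL (exact permutation p = 0.524). Single tumours moved these differences. The FL minus MZL difference of chromosome 14 was -0.11, and -0.07 without FL 1, where its p was smaller (exact permutation p = 0.00216, unadjusted, adjusted p = 0.0675). That of chromosome 13 was -0.14, and -0.06 without MZL 5, -0.08 without MZL 1 and -0.20 without FL 2 (exact permutation p = 0.00866, unadjusted, adjusted p = 0.253). That of X was -0.14, and -0.02 without FL 7, whose match to its skin stays open. On the slide with both types, where most chromosomes were lower in FL, the difference for chromosome 14 was -0.09, and chromosomes 13, 31 and X had the opposite sign to the difference over all slides.

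Against skin, FL tumours were lower in 2 bins, on chromosome 5 from 83000001 (mean log2 ratio -0.22 ± 0.04, SD, limma treat adjusted p = 0.0125) and on chromosome 16 from 55000001 (-0.22 ± 0.03, adjusted p = 0.00889), each in all 7 tumours. No bin passed with mode centring, normexp, the value table, bins of 500 kb, bin medians, a minimum of 0.2 or FL 3 left out, and the bin on chromosome 16 did not pass with the wave removed. Both bins were also low in all 5 MZL tumours (-0.17 ± 0.04 and -0.20 ± 0.03). In MZL no bin passed in limma treat, with 181 bins at an unadjusted p under 0.05, but 7 passed with the slide as a random block, 23 with array weights, 6 on autosomes only, 5 without MZL 5 and 1 in bins of 500 kb, all lower than skin. In FL, 2 bins passed with the slide as a random block. The fitted correlation between arrays of a slide was negative (-0.17). Tumour DNA was always labelled with cyanine 5, so a dye effect of the probes in these bins cannot be told apart from a change in the tumours.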

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

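The tests of wave, noise, X, dye and immunoglobulin genes in this part were chosen only after the results were seen. The bounds for wave and dye on the focal losses were also revised with earlier values known, and reading FL and MZL apart was decided after the percentiles were seen. The counts in other splits of the tumours were planned, but their outcome had been seen when the prediction for each was written down. In 24 groups of values, 1 tumour was compared with the others of its type, and 9 stood apart by the gap to its neighbour. Chance gives about 1 in 20.

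MZL 5 stood apart from the other MZL tumours in 4 related measures. It held 53 called gains, against at most 4 in the others, and 224 called losses, against at most 43. Its gained share of the autosomes was 15.1% and its altered share 37.2%, where the others reached 2.80% and 10.3%. The gained share did not stand apart under other centring or background steps. It was 2.69% with mode centring, 2.64% with normexp and 4.57% in the value table, against 2.77%, 2.76% and 4.72% in MZL 1. Mode centring left 12 called gains and an altered share of 36.6% in MZL 5. In FL, X of FL 7 had a mean log2 ratio of -0.88, where the other FL tumours ranged from -0.32 to 0.06. Chromosome 13 stood at 0.45 in FL 2, chromosome 31 at 0.38 in FL 3 and chromosome 14 at -0.28 in FL 1, each far from the other FL tumours. Chromosome 11 stood at 0.036 in MZL 4, a small distance from the range of -0.017 to -0.0047 of the other MZL tumours.

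Most of the large altered share of MZL 5 was lost with the wave removed. The covariate of the correction was taken from MZL 5 itself, and the model was chosen with its effect on the calls seen. A fall in this array was thus partly built in, and cannot tell a wave from real change. A wave along the chromosomes as the main source stays open. With the wave removed the altered share of MZL 5 was 7.61%, against up to 5.96% in the other tumours (FL 5). MZL 5 then still held 30 called gains and 90 called losses, against at most 15 and 39 in any other tumour. A tumour with more changes than the others thus stays open as well. Probe noise cannot account for the large altered share, since 3 arrays with more noise had smaller altered shares. The gain of chromosome 13 in this tumour is not explained by the wave, since 99.2% of the chromosome was called with the wave removed (mean log2 ratio 0.44). What else may lie behind the 7.61% stays open, and no biological explanation was tested.

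X of FL 7 was low from position 6659620 to its end (mean log2 ratio -0.92), while the stretch before it stood at -0.13, in the range of the other arrays. Loss of a whole X in the tumour would have lowered that stretch of -0.13 as well, as in FL 1 (-0.41). A candidate explanation is that tumour and skin DNA came from different dogs, since FL 7 also held 6 autosomal segments with a mean log2 ratio of 1 or more outside chromosomes 8, 17 and 26, against 0 on each other array. Differences between dogs would run both ways, and it held only 2 such segments of -1 or lower, against 10 in FL 4 and 26 in MZL 5, so this stays open. These counts were made on ratios as measured, with the wave that was strongest in MZL 5. The few low segments in FL 7 thus cannot argue against different dogs. Beyond that position, X relative to the autosomes stood at -0.08 in the skin channel of FL 7 and -1.01 in its tumour channel. The tumour value lay in the range of the tumours with both channels low, from -0.92 to -1.02. Different dogs and a loss of X beyond that position in the tumour could both give these values, so such a loss stays open as well. No biological explanation was tested.

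Deep focal losses on chromosomes 26, 8 and 17, which held them in the most tumours before the wave was removed (11, 8 and 7, against at most 5 on any other autosome), argue against a wave along the chromosomes as their whole cause. Over all of them, kept or not, the median log2 ratio with the wave removed was -0.64, -0.63 and -1.75. On chromosome 8 only 5 of 9 were kept. Some other autosomes, with losses in fewer tumours, stayed as low as chromosomes 26 and 8. Their medians were -0.77 on chromosome 1, -0.70 on 9 and -1.04 on 28. On others the median rose, as on chromosome 20 from -0.69 to -0.42. The depth with the wave removed thus does not set chromosomes 26 and 8 apart. A fixed effect of the dye or the probes would leave the tumours alike, but in stretches placed by the other type and with the wave removed, their spread lay at percentile 99.95 of random windows in FL and 99.99 in MZL on chromosome 26, 99.91 and 95.8 on chromosome 8, and 99.98 and 94.2 on chromosome 17. This argues against a fixed effect as the whole cause on chromosome 26, and in FL on chromosomes 8 and 17. In FL the values on chromosome 17 ran from -0.11 in FL 1 to -1.99 in FL 2. In MZL it does so only narrowly on chromosome 8, with MZL 5 lowest, and on chromosome 17 the question stays open. A fixed effect as part of the cause is not excluded, since a constant offset would leave the spread between tumours unchanged. The chromosomes were chosen for losses seen in both types, so the spread in the other type is not independent of that choice. Rearrangement of immunoglobulin genes may be a source, since the gene table places flanking genes of their loci on these chromosomes, but the 24 of 71 kept losses there (22 of 45 without MZL 5) restate what was seen, and positions of the loci on CanFam3.1 were not used here.

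For FL against MZL, 0 bins passed in limma, and all 100 splits of the tumours examined, the real one included, gave at least 0, as any split must, so this count says nothing about chance. The highest other split also gave 0. At an unadjusted p under 0.05, a count added after the data were seen, 3 of the 100 splits, the real one included, gave at least the real 467 bins, and the highest other gave 799. That count was 190 without MZL 5 and 178 with the wave removed. For FL tumour against skin, 1 of 64 sign patterns, the real one, gave 2 bins, the smallest share these patterns can give, and the highest other gave 0. This argues against chance for the values as measured only. It does not exclude chance, since the rule was written with the outcome known. Also, 0 bins passed with mode centring, normexp, the value table, bins of 500 kb, bin medians, a minimum of 0.2 or FL 3 left out. A dye effect is not excluded either. For MZL, 16 of 16 sign patterns gave at least the real 0 bins (181 at an unadjusted p under 0.05 in limma treat), and the highest other gave 0. These patterns are too few for a share under 0.05.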

How the results depend on the processing

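The wave correction from the skin channel, limma on autosomes only, scanner ratios at the probes of the value table and the count of any call on a chromosome were chosen only after the data were seen. Across settings, 123 values of the main results were the same in direction and side of the threshold, while 20 moved, 13 reversed, 7 became stronger and 6 weaker. With a tumour left out, 139 were the same, 11 moved, 4 reversed, 1 became stronger and 1 weaker. The cause of the changes below was not tested unless stated.

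The FL minus MZL difference in the number of gains changed sign to 2.54 with mode centring, 4.94 with normexp and 1.11 in the value table. That in the number of losses changed to 3.74 in the value table. The difference in the gained share became 0.085 percentage points at a threshold of 0.3, 0.79 with mode centring, 0.43 with normexp, 1.19 in the value table and 0.62 with the wave correction. That in the lost share became 1.19 in the value table and 0.91 with the wave correction, and that in the altered share 2.39 and 1.52. With a tumour left out, these differences ranged from -9.82 to 3.43 gains, from -45.1 to 7.39 losses, from -2.72 to 1.05 points gained, from -5.43 to -0.155 points lost and from -8.15 to 0.90 points altered. Each highest value is that without MZL 5. No exact permutation p of these 5 differences passed 0.05 with 1 choice changed at a time. With the wave removed and MZL 5 left out together, a combination looked at after the data were seen, the altered share was larger in FL by 2.82 percentage points (exact permutation p = 0.0333, unadjusted for the number of settings tried).

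Recurrent loss regions in FL, 9 as measured, numbered 4 at a threshold of 0.3, 2 with a penalty of 1 times the log, 4 with a penalty of 4 times the log, 4 with normexp, 1 in the value table, 5 without saturated or dim probes and 1 with the wave correction. In MZL, 11 regions became 5 at a threshold of 0.3, 18 and 7 with the smaller and larger penalty, 2 with normexp, 1 in the value table, 7 without saturated or dim probes and 1 with the wave correction. In all 12 tumours, 16 regions became 25 at a threshold of 0.15, 3 in the value table and 3 with the wave correction. The value table covers fewer probes. Recurrent gain regions, 0 as measured, numbered 1 in MZL and 3 in all 12 tumours with the wave correction. That on chromosome 20 lay in a recurrent loss region as measured. Leaving out a tumour gave 4 to 9 loss regions in FL (4 without FL 1, 5 without FL 2, FL 3 or FL 4) and 6 to 8 in MZL (7 without MZL 1, 6 without MZL 4 or MZL 5).

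The 2 bins of FL below skin in limma treat became 0 with mode centring, normexp, the value table, bins of 500 kb, bin medians and a minimum of 0.2. They became 1 with the wave correction, 15 with array weights, all lower, and 272 in the plain limma test against 0, of which 39 were higher and 233 lower than skin. In MZL, 0 bins (181 at an unadjusted p under 0.05) became 1 in bins of 500 kb, 23 with array weights, 7 with the slide as a random block, 612 in the plain test (231 higher and 381 lower) and 6 on autosomes only. Leaving out a tumour gave 0 to 10 bins in FL (0 without FL 3, 1 without FL 2, FL 4 or FL 7, 10 without MZL 5) and 0 to 5 in MZL (5 without MZL 5). Bins and chromosomes that differed between FL and MZL numbered 0 in every setting run, limma giving between 7 (the slide as a fixed block) and 617 bins (without MZL 3) at an unadjusted p under 0.05.

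On the slide with both types, the FL minus MZL difference was 0.18 for chromosome 13, -0.049 for chromosome 31 and 0.012 for X, each opposite in sign to that of all slides. Chromosome 11 reached 0.013 with mode centring and 0.00011 with normexp. Chromosome 31 ranged from -0.049 to 0.029 with a tumour left out, the lowest without FL 3. Of the other values of named bins, chromosomes and tumours, 106 across settings and 131 with a tumour left out were the same.

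The correction for GC content was not run, nor were other settings for genes and antigen receptor loci. No paired analysis was possible because the replicate numbers mark different dogs in FL and MZL. Signal over background fell short of the limit of the scanner software on FL 4, MZL 3, MZL 4 and MZL 5, and changes of 30 probes at log2 0.3 were not recovered at the median noise.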

Other observations

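The X signal of each channel was compared with that of the autosomes. In FL 7 the skin stood at a log2 difference of -0.08 and the tumour at -1.01. FL 2, FL 5, MZL 1, MZL 2, MZL 3 and MZL 4 had both channels between -0.92 and -1.02. The remaining tumours had skin between -0.15 and -0.05. MZL 3 held 3 deep losses on X, with mean log2 ratios of -2.30, -2.02 and -1.93.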
